A study of Mus musculus with 22 samples.

How the data were processed

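RNA from 20 mg of frozen non-tumour liver per mouse was hybridised to Affymetrix HT MG-430 arrays, per the labels' protocols. The deposited values are log2 expression values that the authors made with the robust multiarray average (RMA), per the series' design text. By construction RMA corrects background, normalizes quantiles and summarises probes. Probes were grouped by the authors into custom probe sets, 1 for each Entrez gene, per the design text. The software version is not given in the sources used here. Quantile normalization makes arrays alike in their distribution, so a change of all genes together would not be seen, and RMA compresses differences near the background, where most genes lie. Array medians lay between 2.83 and 3.09 with maxima near 12.

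The series holds 13392 genes on 22 arrays. Symbols were taken by Entrez ID from the RefSeq gene table of the GRCm38.p6 assembly, which named 13242 genes, while 150 stayed unnamed. The platform annotation lists 12898. Values are per gene, so no coordinates are given. Many abundant liver genes named in the lists have no value in the deposited data and were not analysed here, and whether the authors filtered genes is not given. The complement list therefore rests on 5 of 30 genes and the acute phase list on 13 of 24. No array was left out, and no filter on low values was applied.

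Groups were taken from the treatment and liver damage labels, giving 3 control, 9 model vehicle and 10 model nintedanib mice, each a separate animal by its title. All 22 arrays were fitted together as 3 group means with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust, 19 residual degrees of freedom). P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Adjusted p-values of genes in the text come from this limma fit, 2-sided. Gene lists (46, fixed before the data were examined, each with at least 5 measured genes) were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. A list score is the mean log2 value of the members in a mouse, compared by exact 2-sided permutation of labels and adjusted over the 46 lists.

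The genes named were set beforehand as the 8 with the largest rise and the 8 with the largest fall that passed in each of the first 2 comparisons, up to 4 members with the smallest p of each list, 8 receptors, 4 in each direction for nintedanib against control, and those that moved back. Clone names were left out. Not every gene under this rule is printed. The subset was picked after the values were seen and favours genes that passed. Dbp, Cebpb and Cebpd fall outside the rule.

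A principal component view showed the runs of title numbers and the pair of arrays described in the results. The labels give no batch, so the boundary between mice 82 and 83, its use as a block and the placing of controls with mice 76 to 82 were all chosen after the data were seen. Of 8 settings added then, 5 used the block or permutation within runs, and the rest used mice 83 to 94 or left out arrays 89 and 91. Alternatives fixed beforehand were a filter on the dimmest 25% of genes, centring on array medians, a repeated quantile normalization, trend and robust variance, array weights, 2-group fits, stricter thresholds, leaving out vehicle mice 92 to 94 and leaving out each mouse.

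The tests were tested on simulated data made from the real means and spreads, with 200 of 13392 genes changed in each of 10 draws. For model vehicle against control, 36.3% of genes changed by log2 0.5, 90.6% of those changed by 1 and 99.7% of those changed by 2 were recovered, with 4.03% false calls. For nintedanib against vehicle the shares were 69.0, 97.8 and 100%, with 5.06% false calls, and for nintedanib against control 38.5, 90.4 and 99.1%, with 4.49%. A shifted list was called in 10 of 10 draws. The simulated genes were independent, so this says nothing of correlated lists.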

Results

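Gene expression was measured in non-tumour liver of 22 male C57BL/6J mice, with 1 Affymetrix HT MG-430 array per mouse. Damaged livers came from a model in which the carcinogen N-nitrosodiethylamine (DEN) and repeated carbon tetrachloride (CCl4), a solvent toxic to hepatocytes, cause fibrosis and hepatocellular carcinoma. There were 3 control mice, 9 model mice given vehicle and 10 model mice given nintedanib, an inhibitor of the vascular endothelial, platelet-derived and fibroblast growth factor receptor kinases. Control mice, with healthy liver, were injected with saline and oil and, by their titles, were also given vehicle. The nintedanib dose was 50 mg/kg, and both model groups were treated for 5 weeks. Levels of 13392 genes were given as log2 values, and array medians lay between 2.83 (mouse 76) and 3.09 (mouse 91). Mice are named by the number in their sample title. The number of arrays limits the precision, above all the 3 controls, and differences below are log2 differences of group means with the standard error of the limma fit.

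The mice fell into 2 runs of title numbers that differed in circadian clock genes. Dbp, a transcription factor driven by the clock, stood at 5.41 ± 0.37 (SD, n = 6) in vehicle mice 76 to 81 and at 9.18 ± 0.11 (SD, n = 3) in vehicle mice 92 to 94. Arntl, which encodes the core clock activator BMAL1, stood at 6.04 ± 0.10 and 3.21 ± 0.31 in the same mice. Nintedanib mouse 82 had 6.19 for Dbp and 6.01 for Arntl, while nintedanib mice 83 to 91 had means of 9.08 ± 0.17 and 3.37 ± 0.26 (SD, n = 9). The controls, at 5.59 ± 0.53 and 6.47 ± 0.25 (SD, n = 3), lay near mice 76 to 82. Of the 9 vehicle mice 6 belonged to the run 76 to 82, against 1 of the 10 nintedanib mice, so that treatment and run overlapped strongly. Many nintedanib differences are therefore given also with the run as a block or within mice 83 to 94. Nintedanib gene differences printed alone are without the block. These 2 genes were singled out after their values were seen. Arrays 89 and 91, both from nintedanib mice, stood apart from the rest, with median correlations to the other arrays of 0.950 and 0.948 and log2 medians of 3.05 and 3.09.

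**Figure D1:**
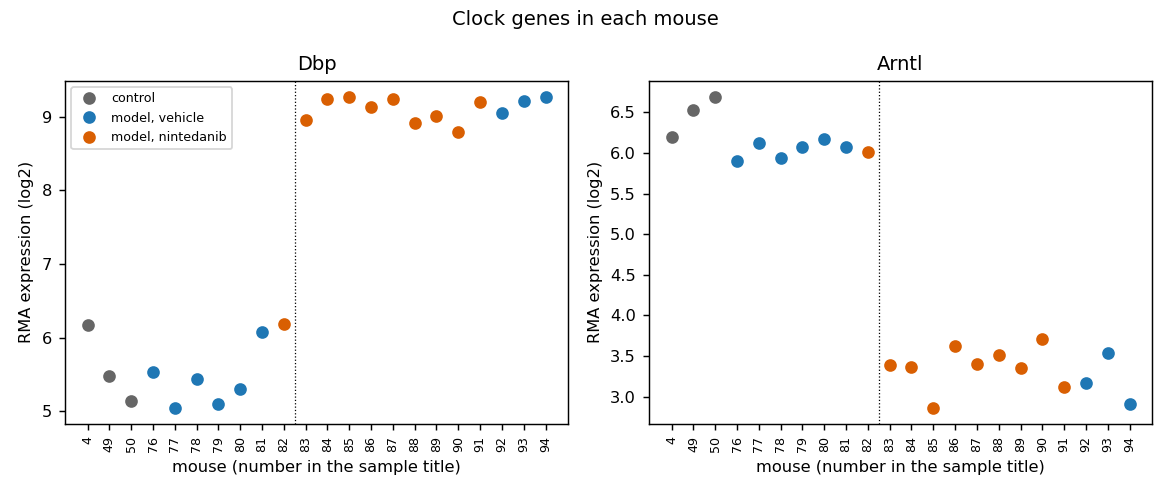
Expression (log2) of Dbp and Arntl in each mouse, ordered by title number, with a dotted line between mice 82 and 83. Dbp means were 5.41 in vehicle mice 76 to 81 and 9.18 in vehicle mice 92 to 94, and Arntl means were 6.04 and 3.21.

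The comparison of vehicle-treated model mice with controls asks what DEN and CCl4 did to the liver. The controls had title numbers 4, 49 and 50, outside the model mice's 76 to 94, and the labels give no batch. A difference of batch or collection between controls and model mice cannot be told apart from the model effect. Matrix, macrophage, antigen presentation and proliferation genes were higher in the model, and genes typical of male liver were lower (9 model mice, 3 controls). Col1a2, a chain of type I collagen, rose by 1.96 ± 0.19 (adjusted p = 4.99e-07). Gpnmb, a glycoprotein of macrophages in injured tissue, rose by 2.33 ± 0.33 (adjusted p = 0.000103). Susd4, a complement regulator with higher expression in male liver, fell by 3.48 ± 0.19 (adjusted p = 1.35e-11). In all, 338 of 13392 genes changed at an adjusted p under 0.05, 208 higher and 130 lower in the model.

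Of 36 measured collagen and matrix genes 15 rose, none fell and 21 did not pass, or 22 adjusted over the list alone (adjusted list p = 2.07e-22). They included lumican (Lum, 1.54 ± 0.19), the type III collagen chain Col3a1 (1.37 ± 0.18) and dermatopontin (Dpt, 1.85 ± 0.26). Among matrix remodelling genes 5 of 23 rose, or 11 adjusted over the list alone, and none fell (adjusted list p = 5.85e-08). Examples were the gelatinase Mmp2 (1.42 ± 0.22), the macrophage elastase Mmp12 (2.02 ± 0.38) and the plasminogen activator Plat (0.92 ± 0.21). Stellate cell and myofibroblast genes, 4 of 21 of which rose, shifted upward (7 higher and 1 lower adjusted over the list alone, adjusted list p = 0.000132), with Vim, an intermediate filament gene, at 0.93 ± 0.19 and the pericyte marker Rgs5 at 0.59 ± 0.15.

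Monocyte-derived macrophage genes rose in 7 of 22 cases, or 16 adjusted over the list alone (adjusted list p = 3.64e-16), among them Lgals3, which encodes galectin-3 (1.07 ± 0.19), and Ms4a7 (1.64 ± 0.30). MHC class II genes rose in 5 of 10 cases, or 8 adjusted over the list alone (adjusted list p = 7.22e-11). The class II chain H2-Eb1 was higher by 0.85 ± 0.14 and the invariant chain Cd74 by 0.67 ± 0.14. Cytotoxic and NK cell genes (2 of 24 rose, 3 adjusted over the list alone) had an adjusted list p of 0.00496 and an adjusted p = 0.110 with an estimated correlation. They included Ccl5, a chemokine that attracts T cells (1.89 ± 0.34), and the NK receptor gene Klrd1 (0.84 ± 0.20). B and plasma cell genes (4 of 24 rose, 6 adjusted over the list alone) had an adjusted list p of 0.00478 and an adjusted p = 0.130 with an estimated correlation, with the B cell adaptor Blnk at 1.12 ± 0.26. Neutrophil genes (2 of 19 rose, 3 adjusted over the list alone) had an adjusted list p of 0.000836 and an adjusted p = 0.110 with an estimated correlation. The 2 genes were S100a8 (1.93 ± 0.24) and S100a9 (1.35 ± 0.31), the subunits of calprotectin. T cell genes as a list did not shift (adjusted p = 0.359), with 1 of 28, the adaptor Skap1, lower by -0.48 ± 0.12. The checkpoint and exhaustion list (adjusted p = 0.631) also held 1 gene that fell, Ido1, a tryptophan-degrading enzyme (-0.50 ± 0.11), among 21, or 1 higher and 2 lower adjusted over the list alone. Both were dim genes, with control means of 2.82 and 2.63. The T cell and checkpoint scores, with control means of 2.70 and 3.00, also lay near the array medians, so a shift of these lists could be missed. The interferon-gamma list showed no shift (adjusted p = 0.676).

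Endothelial genes shifted upward (adjusted list p = 7.96e-06), with 1 of 18 past the threshold over all genes and 3 adjusted over the list alone. That gene was Pecam1, an endothelial adhesion molecule (0.79 ± 0.21, adjusted p = 0.0438), which passed in 10 other settings and did not in 12. Sinusoidal endothelial genes (1 of 12, also 1 adjusted over the list alone) had an adjusted list p of 0.0375 and an adjusted p = 0.336 with an estimated correlation, with the hyaluronan receptor gene Lyve1 at 0.97 ± 0.21. The Kupffer cell list did not pass (adjusted p = 0.168, and 0.0101 with the block, where it had an adjusted p = 0.402 with an estimated correlation), with 2 of 13 genes lower and none higher over all genes, and 3 higher and 2 lower adjusted over the list alone. One of those that fell was Cd163, a haemoglobin scavenger receptor (-0.88 ± 0.20). None of the 8 receptor genes fixed beforehand as nintedanib targets passed the threshold. The differences ran from -0.06 ± 0.14 for Flt1 to 0.51 ± 0.16 for Pdgfra (adjusted p = 0.0845). Among their ligands Fgf1 fell by 1.03 ± 0.17.

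Proliferation, tumour marker and metabolic lists shifted as well. Cell cycle genes shifted upward (4 of 34, also 4 adjusted over the list alone, adjusted list p = 1.56e-07), including cyclin D1 (Ccnd1, 1.54 ± 0.25) and the mitotic kinase Cdk1 (1.26 ± 0.30). Fetal liver and carcinoma markers rose in 5 of 22 cases, or 6 adjusted over the list alone (adjusted list p = 7.96e-06), among them the Golgi protein Golm1 (0.99 ± 0.14), the progenitor marker Prom1 (1.36 ± 0.23) and Ly6d (1.96 ± 0.41). NRF2 and glutathione genes rose in 3 of 13 cases, or 7 adjusted over the list alone (adjusted list p = 1.93e-07), led by the glutathione transferase Gstm3 (1.79 ± 0.23). Male-biased liver genes fell in 5 of 16 cases, or 12 adjusted over the list alone (adjusted list p = 2.29e-13). Besides Susd4 they included Hsd3b5, a steroid dehydrogenase of male liver (-3.86 ± 0.74), Cyp7b1, an oxysterol hydroxylase (-2.49 ± 0.32), and Cyp2u1 (-1.28 ± 0.23). Female-biased genes (2 of 18 rose, 5 adjusted over the list alone) had an adjusted list p of 0.00355 and an adjusted p = 0.132 with an estimated correlation, with the peroxisomal transporter Abcd2 at 1.42 ± 0.20. The list of PPAR-alpha and fatty acid oxidation genes had an adjusted p of 0.00869 and an adjusted p = 0.448 with an estimated correlation, with 1 of 17 genes higher over all genes and 3 higher and 1 lower adjusted over the list alone.

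Pericentral hepatocyte genes moved both ways, and the list did not shift (1 of 18 higher and 4 lower, or 4 and 5 adjusted over the list alone, adjusted p = 0.475). The ornithine aminotransferase Oat (-1.64 ± 0.28), the glutamate transporter Slc1a2 (-1.31 ± 0.27) and glutamine synthetase (Glul, -0.87 ± 0.19) fell, while Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 1.39 ± 0.29. Other genes with large changes were Apoa4, an apolipoprotein (2.28 ± 0.17), the metallothionein Mt2 (1.85 ± 0.43), the lipid droplet protein gene Fitm1 (-3.55 ± 0.30), Cnmd (-2.75 ± 0.38), the transcription factor Olig1 (-2.32 ± 0.40), the protease inhibitor Serpine2 (-1.93 ± 0.25) and Adh6-ps1 (-1.91 ± 0.26).

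Of 46 lists 16 shifted, 15 upward and 1 downward, and 10 did so with an estimated correlation. The median over 99 other splits of the 12 mice was 7 lists, so the preset correlation may be liberal here. Many of these splits still divide model and control mice unevenly, so part of that count can come from the model effect. In exact permutation tests of the list score, the mean of a list's members in each mouse, 13 lists differed. With 3 controls such a test cannot give a p below 0.00455, which was the p for collagens, macrophages and male-biased genes, among others. Matrix scores were 4.74 ± 0.12 in vehicle mice and 4.17 ± 0.05 in controls (SD, n = 9 and n = 3).

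**Figure D2:**
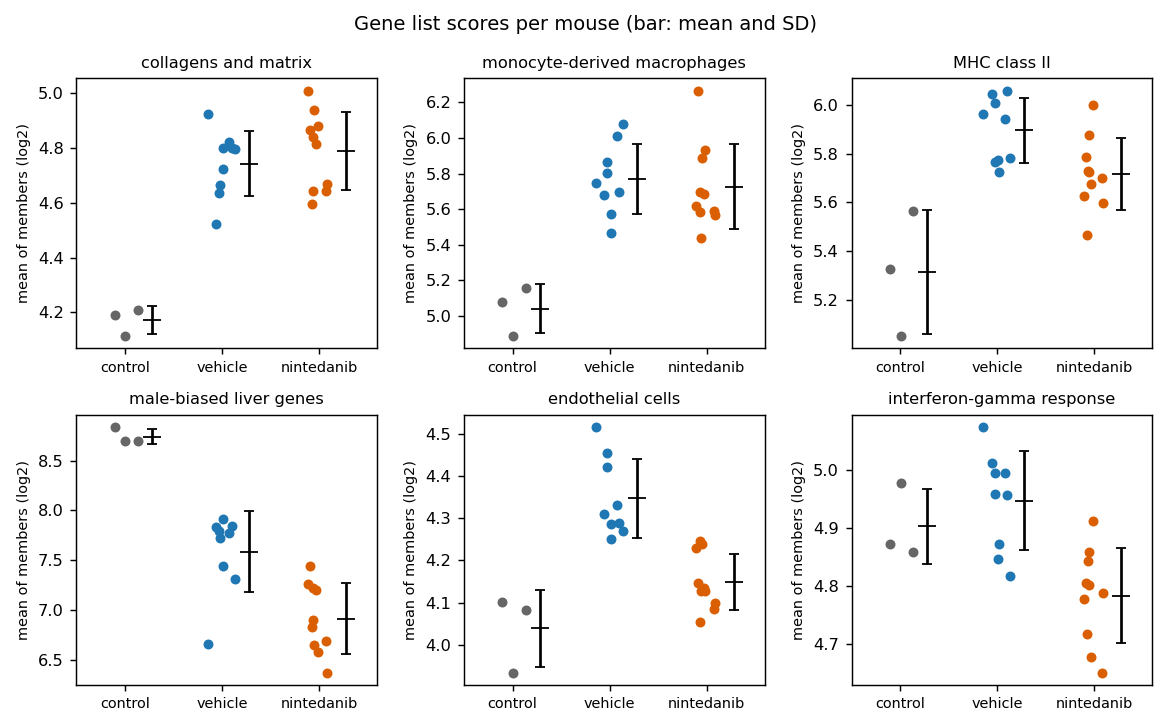
Score per mouse (mean log2 value of a list's members) for 6 lists in control, vehicle and nintedanib mice, each point a mouse, with the group mean and SD as a bar. The collagen and matrix score had means of 4.17, 4.74 and 4.79 in these groups, and the endothelial score 4.04, 4.35 and 4.15.

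The comparison of nintedanib with vehicle in model mice asks what the drug changed in damaged liver. The metallothioneins Mt2 and Mt1, which bind zinc and copper, rose by 2.89 ± 0.30 and 2.07 ± 0.23 under nintedanib (adjusted p = 7.47e-06 and 1.46e-05, 10 nintedanib and 9 vehicle mice). With the run as a block they were higher by 2.66 and 1.89 (adjusted p = 0.00185 and 0.00219), and within mice 83 to 94 by 2.27 and 1.56. Lpin1, a phosphatidate phosphatase of triglyceride synthesis, rose by 1.49 ± 0.19 (1.11 with the block, adjusted p = 0.0258, and 1.11 within mice 83 to 94). Endothelial and interferon-gamma genes shifted downward as lists, while collagen and matrix genes did not shift.

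Without the block 92 genes changed, 55 higher and 37 lower. With the block 6 genes passed, all higher under nintedanib, and the count at an unadjusted p under 0.05 fell from 1417 to 663. Within mice 83 to 94 (9 nintedanib, 3 vehicle) limma called 0 genes, with 695 at an unadjusted p under 0.05. The 6 genes were Mt2, Mt1, Lpin1, Tox, Cebpb and Cebpd. Tox, a transcription factor known from exhausted T cells and a member of the checkpoint list, rose by 0.61 ± 0.08 (0.56 with the block, adjusted p = 0.0390, and 0.61 within mice 83 to 94). Cebpb and Cebpd, which encode transcription factors of the acute phase response and were singled out after their values were seen, rose by 0.67 ± 0.08 and 0.79 ± 0.14. With the block they were higher by 0.72 and 0.91 (adjusted p = 0.00219 and 0.0344), and within mice 83 to 94 by 0.77 and 0.94.

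The other genes passed without the block only. The female-biased cytochrome Cyp2b9 was higher by 1.91 ± 0.33 (adjusted p = 0.00727), by 1.97 with the block (adjusted p = 0.124) and by 1.60 within mice 83 to 94. The clock output gene Usp2 was higher by 2.25 ± 0.52 without the block and by 0.43 with it, and the rhythmic deadenylase-like gene Noct by 1.61 ± 0.29 and 0.75. Fmo2, a flavin monooxygenase, had 1.05 ± 0.22 and 0.63. On the other side, the fatty acid elongase Elovl3 differed by -2.75 ± 0.53 without the block and -1.35 with it, and the glycogen-targeting subunit Ppp1r3c by -1.78 ± 0.33 and -1.26. The values were -1.56 ± 0.37 and -0.79 for the hepatic hormone Fgf21, -1.44 ± 0.30 and -0.61 for Tubb2a, and -1.29 ± 0.22 and -1.12 for the organic anion transporter Slco1a1. Id1, a target of bone morphogenetic protein signals, had -1.01 ± 0.24 and -1.24, Il1a -0.98 ± 0.20 and -0.79, and the tight junction gene Cldn1 -0.95 ± 0.19 and -0.43. Within mice 83 to 94 these genes ran from -1.71 for Id1 to 0.75 for Fmo2, Cyp2b9 apart, and each kept its sign.

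**Figure D3:**
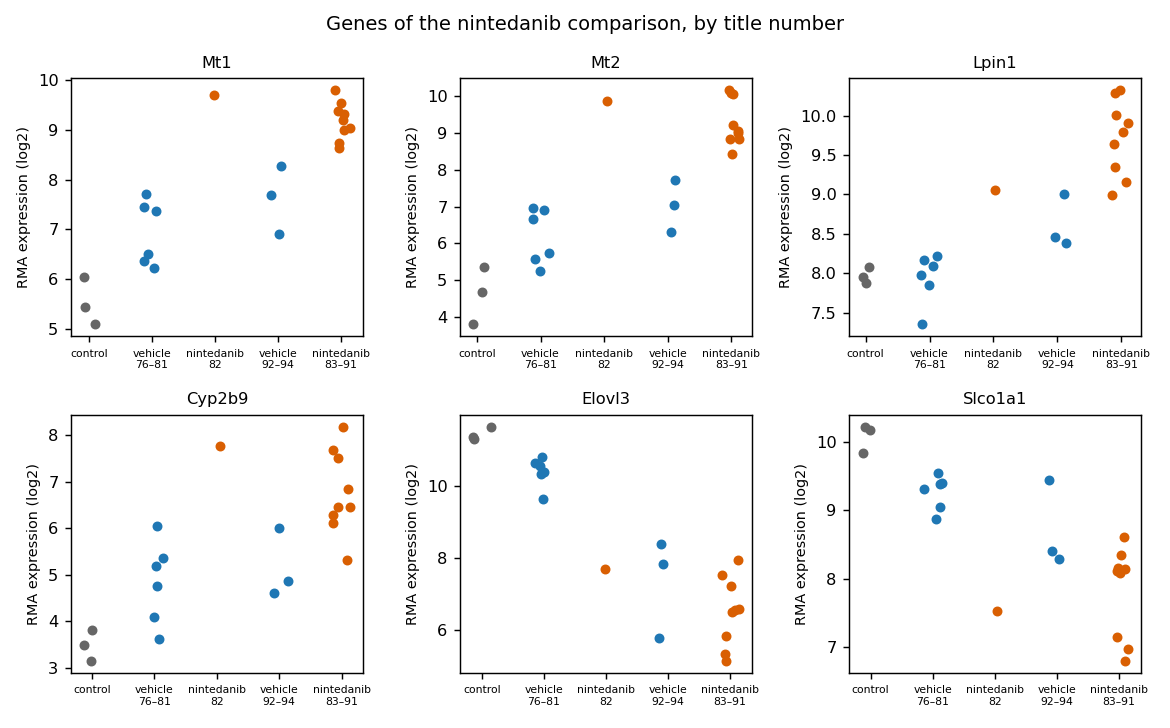
Expression (log2) of 6 genes in each mouse, grouped by treatment and title number, each point a mouse. Mt2 differed by 2.27 within mice 83 to 94 and by 3.69 between mouse 82 and vehicle mice 76 to 81, while Elovl3 differed by -0.82 and -2.72.

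Vascular genes were lower as a group. Of 18 endothelial genes 1 fell, the tight junction gene Cldn5 (-0.61 ± 0.14, adjusted p = 0.0320, and -0.53 with the block, adjusted p = 0.568), and 4 fell adjusted over the list alone. The list shifted downward without and with the block (adjusted p = 8.97e-06 and 8.35e-05). Further members had -0.50 ± 0.15 (Pecam1), -0.28 ± 0.08 (Kdr, the main VEGF receptor) and -0.25 ± 0.07 (Tek, the angiopoietin receptor), none of which passed over all genes (adjusted p = 0.119 for each). The endothelial score lay between 4.05 and 4.25 in nintedanib mice and between 4.25 and 4.52 in vehicle mice, without overlap. Its difference was -0.24 within mice 83 to 94 and -0.09 between mouse 82 and vehicle mice 76 to 81. Permuting labels within runs gave p = 0.000649, the smallest these permutations can give (adjusted p = 0.0299). Sinusoidal endothelial genes also shifted downward (none of 12 passed, 5 fell adjusted over the list alone, adjusted list p = 2.14e-06 and 0.0191 with the block, and with the block an adjusted p = 0.208 with an estimated correlation). Their score differed by -0.10 within mice 83 to 94. None of the 8 target receptors passed the threshold. Apart from Kdr the values ran from -0.28 ± 0.09 (Flt1) to 0.03 ± 0.11 (Fgfr3), with signs that depended on the fit for Pdgfra, Pdgfrb, Fgfr1, Fgfr2 and Fgfr3.

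Some immune lists shifted downward, and others did not. In the interferon-gamma list none of 20 genes passed and 5 fell adjusted over the list alone, with an adjusted list p of 0.000131 and of 9.47e-05 with the block. Its member Irgm2, an interferon-inducible GTPase, had -0.58 ± 0.15 (adjusted p = 0.0669). The list score differed by -0.19 within mice 83 to 94. Weighted over both runs it differed by -0.17 (permutation within runs, p = 0.00260, adjusted p = 0.0299). The type I interferon list (none of 21 passed, 3 lower adjusted over the list alone) had an adjusted list p of 0.00243 and an adjusted p = 0.119 with an estimated correlation. MHC class II (none of 10, also none adjusted over the list alone) had an adjusted list p of 0.00111 and an adjusted p = 0.241 with an estimated correlation. B and plasma cell genes (1 of 24 fell, also 1 adjusted over the list alone) had an adjusted list p of 0.000749 and an adjusted p = 0.0790 with an estimated correlation. That gene was Jchain, the joining chain of polymeric antibodies (-0.73 ± 0.17, and -0.47 with the block). With the block the adjusted p of these 3 lists was 0.0198, 0.00846 and 0.000314, and their scores differed by -0.09, -0.19 and -0.15 within mice 83 to 94. The Kupffer cell list (none of 13 passed, 1 lower adjusted over the list alone) had an adjusted p of 0.000305, an adjusted p = 0.299 with an estimated correlation, and 0.608 with the block. T cell (adjusted p = 0.351), cytotoxic (0.513), checkpoint (0.665), monocyte-derived macrophage (0.332) and neutrophil lists (0.581) did not shift. The T cell, cytotoxic and checkpoint scores had means of 2.73, 2.95 and 3.01 with nintedanib, near the array medians. A shift of these lists could therefore be missed.

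Collagen and matrix genes had a median difference of 0.04 (none of 36 passed, adjusted list p = 0.438), and stellate cell genes of -0.00 (none of 21 passed, 1 higher adjusted over the list alone, adjusted list p = 0.654). Lum, the matrix gene with the smallest p, had 0.37 ± 0.13 (adjusted p = 0.245). Matrix scores were 4.79 ± 0.14 with nintedanib and 4.74 ± 0.12 with vehicle (SD, n = 10 and n = 9). Cell cycle (adjusted p = 0.110) and carcinoma marker lists (adjusted p = 0.411) did not pass.

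Metabolic lists moved in several directions. Male-biased genes fell further under nintedanib (3 of 16, or 10 adjusted over the list alone, adjusted list p = 8.49e-11, and 7.42e-10 with the block), with an adjusted p = 0.0582 with an estimated correlation. Elovl3, Slco1a1 and the complement gene C6 (-0.65 ± 0.14) were the 3 genes, none of which passed with the block, and the score differed by -0.35 within mice 83 to 94. Female-biased genes (2 of 18 rose, 3 adjusted over the list alone, adjusted list p = 0.00171) had an adjusted p = 0.124 with an estimated correlation and 0.102 with the block. Clock genes rose in 5 of 22 cases (14 higher and 2 lower adjusted over the list alone, adjusted list p = 1.43e-08). With the block none passed, the median fell from 0.60 to 0.15, and the list kept an adjusted p of 9.15e-05. The period gene Per1 had 0.99 ± 0.18 without the block and 0.59 with it, Tspan4 0.59 ± 0.11 and 0.37, and the output factor Hlf 0.68 ± 0.14 and 0.32. The clock score differed by 0.16 within mice 83 to 94. Weighted over both runs it differed by 0.20 (permutation within runs, p = 0.00325, adjusted p = 0.0299).

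The drug metabolism list of CAR, PXR and AhR targets (1 of 18 rose, 4 adjusted over the list alone, adjusted list p = 0.00171, and 0.000802 with the block) had an adjusted p = 0.0721 with an estimated correlation. Its gene was Por, the electron donor of cytochromes P450 (0.94 ± 0.18, and 0.40 with the block), and its score differed by 0.20 within mice 83 to 94. The acute phase list (2 of 13 rose, 3 higher and 1 lower adjusted over the list alone, adjusted list p = 0.000749, and 0.000245 with the block) had an adjusted p = 0.338 with an estimated correlation. The 2 genes were Mt1 and Mt2, and without them p was 0.173. Fatty acid synthesis genes (1 of 17 rose, Lpin1, and 3 adjusted over the list alone, adjusted list p = 0.0106, and 0.0395 with the block) had an adjusted p = 0.338 with an estimated correlation and a median of -0.06 within mice 83 to 94. Endoplasmic reticulum stress genes (none of 11 passed, 7 fell adjusted over the list alone, adjusted list p = 0.000426) had an adjusted p = 0.0721 with an estimated correlation and 0.0680 with the block. The 5 measured complement and coagulation genes (C6 fell, 2 adjusted over the list alone, adjusted list p = 0.00424, and 0.000132 with the block) had an adjusted p = 0.0790 with an estimated correlation. The p53 list passed with the block only (median 0.35, adjusted p = 1.04e-06, against 0.0558 without it). Its gene past the threshold without the block, the kinase Plk2, went the other way (-0.66 ± 0.12).

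In all, 15 of 46 lists shifted, 5 upward and 10 downward, and 4 did so with an estimated correlation, namely the endothelial, sinusoidal endothelial, interferon-gamma and clock lists. The median over 99 other splits of the 19 mice was 5 lists. With the block 13 lists shifted, 12 of them as before. List scores differed for 12 lists in exact permutation tests, and for 5 when labels were permuted within runs (endothelial, interferon-gamma, p53, clock and complement).

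**Figure D4:**
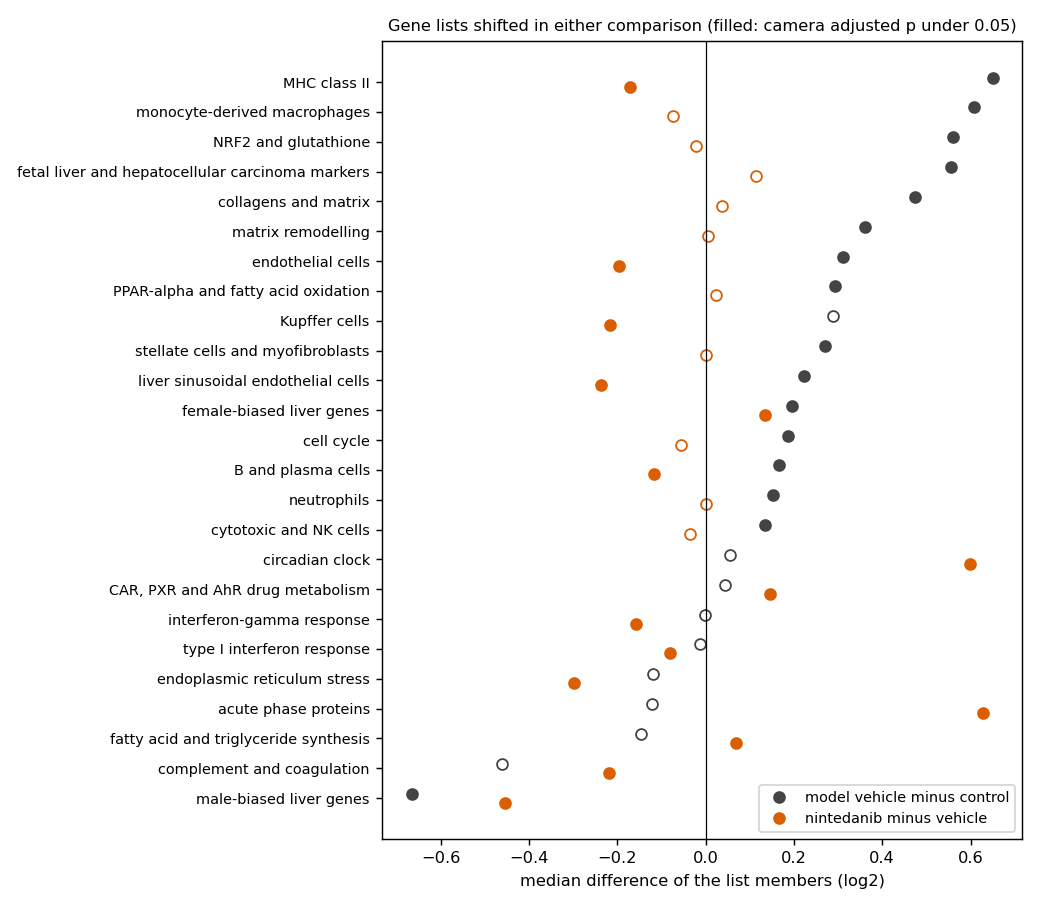
Median log2 difference of the members of each list that shifted in either comparison, for model vehicle minus control and for nintedanib minus vehicle without the run as a block; filled points have a camera adjusted p under 0.05. Matrix genes had medians of 0.47 and 0.04, and endothelial genes 0.31 and -0.20.

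The comparison of nintedanib-treated model mice with controls gives the distance of treated from healthy liver. It called 784 genes, 384 higher and 400 lower, and 244 with the block (10 nintedanib mice, 3 controls). Mt2 and Mt1 were the genes with the largest rises, by 4.74 ± 0.42 and 3.72 ± 0.33 (4.38 and 3.44 with the block), followed by Usp2 (3.64 ± 0.75, and 0.76 with the block, adjusted p = 0.195) and Cyp2b9 (3.38 ± 0.47, and 3.46). Hsd3b5 fell by 5.39 ± 0.73 (-5.02 with the block), Elovl3 by 4.83 ± 0.75 (-2.59), Fitm1 by 3.74 ± 0.30 (-3.72) and Susd4 by 3.62 ± 0.19 (-3.56). Matrix genes stayed above control (18 of 36 rose), as did macrophage genes (9 of 22), and male-biased genes stayed below (10 of 16 fell). The block puts the controls with mice 76 to 82, since their clock genes lay there, and the labels do not give their run.

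Of the 338 genes changed in model vehicle mice against controls, 177 had a nintedanib difference of the opposite sign, or 52.4% (exact binomial interval 46.9 to 57.8%, which treats genes as independent). The vehicle mice enter both differences, and simulated mice without a nintedanib effect gave 55.6% (49.7 to 60.7%). With different vehicle mice used for the 2 differences the median share over 100 draws was 51.2%. The 338 genes were still those chosen with all vehicle mice, so these draws do not fully remove the shared use. With the block, which changes the set of model genes, it was 176 of 390, or 45.1%. Of these genes 4 passed in both comparisons with opposite signs, namely the antibody genes Igha, Igkc and Jchain and the tubulin Tuba8, and 10 passed with the same sign, where the simulated mice gave medians of 0 and 0. Igha rose by 1.36 ± 0.25 in the model and fell by 0.78 ± 0.17 under nintedanib, Igkc by 1.08 ± 0.24 and 0.76 ± 0.17, and Tuba8 by 1.61 ± 0.16 and 0.47 ± 0.11. None of the 4 passed for nintedanib with the block, where the differences were -0.48, -0.60, -0.48 and -0.47 for Igha, Igkc, Tuba8 and Jchain. By direction, 8 genes were higher in both comparisons against 0.854 for independent lists, and 4 were higher in the model and lower under nintedanib against 0.575. None was lower and then higher, against 0.534, and 2 were lower in both, against 0.359. The covariance of the 2 differences over all genes was -0.000139, against -0.00848 in the simulation, a gap of 0.00834. The simulation leaves out effects of the drug, the independent lists leave out the shared vehicle mice, and both leave out the run. An excess over either is therefore not a measure of shared effects. With the block 0 genes passed in both comparisons with opposite signs and 2 with the same sign.

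The study's title speaks of mice that respond, so the spread of list scores was compared between nintedanib and vehicle mice. None of 46 lists differed in spread by an exact permutation test after adjustment, and 1 had an unadjusted p under 0.05, the acute phase list (SD 0.810 with nintedanib and 0.306 with vehicle, exact p = 0.0183, adjusted p = 0.843). The test did not allow for the run, which divided the vehicle mice more evenly than the nintedanib mice, nor for arrays 89 and 91. The clock score, for example, had an SD of 0.373 with vehicle and 0.212 with nintedanib. The test therefore does not show whether some treated mice responded.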

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

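Tests in this part on the clock difference (nintedanib, array batch) and on the 6 genes that passed in both fits were written after their results were seen, and the others before.

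In each group of 9 or 10 mice, a set of the named genes, some list scores and the array median were checked for a mouse far from the rest. The measure was the gap to its neighbour divided by the whole range. The scores were those of the T cell, cytotoxic, checkpoint, B cell, interferon-gamma, matrix, stellate, endothelial and cell cycle lists. Dbp, Arntl and the other list scores, that of the clock among them, were not checked. Of 196 groups checked 16 stood out, where chance gives about 1 in 20, or 9.8. Among vehicle mice these were Ms4a7 (0.534) and the B and plasma cell score (0.689) in mouse 80, S100a9 (0.572) in mouse 78, and Ccnd1 (0.604) and Abcd2 (0.564) in mouse 92. Among nintedanib mice they were Mmp12 (0.540) and Lgals3 (0.528) in mouse 88, Vim (0.480) in mouse 89, Golm1 (0.518) in mouse 91 and Abcc4 (0.496) in mouse 90. In mouse 82 there were 6 among the items checked, namely Cd163 (0.604), Usp2 (0.793), Noct (0.619), Cldn1 (0.530), Hlf (0.517) and Por (0.559). Dbp and Arntl also stood apart in mouse 82, at 6.19 and 6.01. Nintedanib mice 83 to 91 had 8.79 to 9.26 and 2.86 to 3.71. Mouse 82 is the only nintedanib mouse with a title number in the run 76 to 82.

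Clock genes separated mice 76 to 82 from mice 83 to 94. Between vehicle mice of the 2 runs Dbp minus Arntl differed by 6.61, with a pooled SD of 0.394, so nintedanib, which neither received, is excluded as its cause. Of 22 clock genes 63.6% differed between the runs with treatment in the model, against 1.87% of all genes. This argues against an array batch that moves genes without regard to the clock as the cause of the clock difference. The boundary was chosen after the data were seen, and only 14 of the 250 genes that differed were clock genes. A batch that moved the other genes is therefore not excluded. A different hour of tissue collection was not tested, as the labels give no times.

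The run may account for part of the 92 genes of nintedanib against vehicle. For the 5 clock genes among them the median ratio of the difference with the block to that without it was 0.465. That met the bound written beforehand for the run as the whole cause. The run as the whole cause thus remains possible for these 5 genes. Simulated mice with a run effect alone gave 0.621 to 0.926 over all called genes, which is no reference for clock genes. Over all 92 the ratio was 0.668, which cannot tell, because simulated mice with a run effect alone gave 0.793 (0.621 to 0.926) in the 17 of 100 draws with a value. The same simulation gave a median of 0 changed genes (0 to 14.7), and 0 of 100 draws reached 92. It was added after the ratio over all 92 was seen, when the bound written beforehand against the run had been met. It rests on the run effect as modelled, so its counts alone exclude nothing. The block removes a run effect of equal size in all mice, yet 6 genes passed in both fits. This argues against such an effect as the whole cause. It does not exclude one, as another split within the runs gave 16 genes with the block. Without arrays 89 and 91, 49 genes remained, which excludes these arrays as the whole cause.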

How the results depend on the processing

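The 3 controls, the overlap of treatment with run and weak signal over background in most genes limit precision. Settings using the block, mice 83 to 94 only, permutation within runs, or leaving out arrays 89 and 91 were added after seeing the data. No paired analysis was possible because the groups share no title numbers. Unless its own construction shows it, the cause was not tested.

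An adjusted p under 0.01 left 155 genes for model against control, 21 for nintedanib against vehicle and 352 genes changed in model nintedanib against control. A change of 1.5-fold left 59 for nintedanib against vehicle. An estimated correlation left 10 and 4 lists. Without vehicle mice 92 to 94 nintedanib against vehicle gave 380 genes, and 62.5% of model-changed genes moved back under nintedanib. With the block it gave 6 genes, nintedanib against control 244, and 45.1% moved back. Without arrays 89 and 91 it gave 60. With the block and without these arrays the counts were 527 for model against control, 5 for nintedanib against vehicle and 358 for nintedanib against control. With the block in the 19 model mice it gave 5, also without these arrays. Within mice 83 to 94 limma gave 0 (695 at an unadjusted p under 0.05), and also 0 without these arrays (876). List scores as medians differed for 6 lists (model) and 4 (nintedanib), and for 5 with permutation within runs. Other settings fixed beforehand kept each count within 1.5-fold.

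Leaving out 1 mouse gave 146 to 344 genes for model against control, lowest without control 50 (158 without control 4). For nintedanib against vehicle it gave 49 to 230, with 49 without mouse 76, 57 without 77, 59 without 78, 56 without 79, 58 without 81, 59 without 84, 155 without 93, 184 without 94 and 230 without 82. For nintedanib against control it gave 379 to 852, with 379 without control 4 or control 50. Lists ranged from 14 to 18 (model) and 15 to 17 (nintedanib), and list scores from 0 to 13 (model) and 9 to 15 (nintedanib). The 0 came when any 1 control was left out. The smallest p the exact test can give is then higher, so this 0 does not show that the differences rest on 1 control. The share of model-changed genes moved back under nintedanib ranged from 48.4 to 59.6%.

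Some calls of genes named in the text were lost in most settings. For nintedanib against vehicle those of Usp2, Tuba8 and Jchain were lost in 24 settings and kept in 9, that of Id1 in 23 and 10, and that of Fgf21 in 22 and 11.

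Signs turned only in small differences. For nintedanib against vehicle Fgfr1 had -0.00328 centred, -0.0134 with array weights, -0.0725 with the block (also in model mice), -0.0580 within mice 83 to 94, -0.0228 without arrays 89 and 91, -0.107 with the block and without these arrays, and -0.106 within mice 83 to 94 without them. Fgfr3 had -0.0130 with weights, and in the other settings -0.104, -0.123, -0.0242, -0.147 and -0.18. Pdgfrb had 0.0316 quantile normalized again, 0.0153 without mice 92 to 94, 0.0624 with the block, 0.0447 without arrays 89 and 91 and 0.0978 with both. Pdgfra had 0.00433 with the block and 0.0538 with both, and Fgfr2 0.000166 without mice 92 to 94. For model against control Fgfr1 had -0.0316 without mice 92 to 94, -0.0371 with the block and -0.0321 with both, Fgfr3 -0.00197 without mice 92 to 94, and Flt1 0.000584 with the block and 0.00860 with both. The median of the list fatty acid and triglyceride synthesis was -0.0624 within mice 83 to 94 and -0.13 also without these arrays, while the list Kupffer cells kept a negative median, -0.00360, with the block and without these arrays, where its camera direction turned upward. Leaving out 1 mouse gave, for nintedanib, -0.0265 to 0.0591 (Fgfr1), -0.0108 to 0.10 (Fgfr3) and -0.0497 to 0.0543 (Pdgfrb), and for the model -0.0112 to 0.0705 (Fgfr1), -0.0467 to 0.20 (Fgfr3) and -0.11 to 0.000952 (Flt1).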

Other observations

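In this part the test of the endothelial list against the run was written after its result was seen, and the other tests before.

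Between the runs, with treatment left out of the model, 507 genes differed, 272 higher and 235 lower in mice 83 to 94. With treatment in the model 250 differed. Arntl differed by -2.78, Dbp by 3.50, Usp2 by 3.21, Ciart, a clock repressor, by 2.69, the cell cycle kinase Wee1 by 2.03 and the period gene Per2 by 1.99. These genes were chosen after their values were seen.

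Endothelial genes were lower under nintedanib. With the run as a block the list kept an adjusted p of 8.35e-05, and 0.000404 also without arrays 89 and 91, so neither the run as modelled nor these arrays can be the whole cause. The endothelial minus the stellate score differed by -0.29 (exact permutation within runs, p = 0.000649, the smallest these permutations can give). This argues against an equal loss of all cells other than hepatocytes. It does not exclude one, as only stellate genes were compared and a score also depends on expression per cell. Lower VEGF receptor signalling was not tested, and fewer endothelial cells and lower expression per cell were not told apart.

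Mt1 and Mt2 were higher under nintedanib, and 3 lists of possible causes were added after that was seen, with predictions written before their tests. Glucocorticoid targets shifted upward with the run as a block (p = 8.56e-05, adjusted p = 0.000257, 13 of 14 genes above 0, none past the threshold), and had p = 0.0215 (adjusted p = 0.0645) without it. Fasting and glucagon genes had p = 0.0307 with the block (adjusted p = 0.0460), p = 0.220 with an estimated correlation and p = 0.510 without the block. Metal and zinc genes had p = 0.600 with 6 measured, which cannot tell. Both of the first 2 responses remain possible by these list tests and were not told apart, since 5 of the 14 glucocorticoid genes (Pck1, G6pc, Angptl4, Igfbp1 and Irs2) are also in the fasting list.

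Counts were compared with those of other splits of the same mice, 100 with the real one included. For model against control 1 split reached the 338 genes (highest other 5) and 2 reached the 16 lists (highest other 16). For nintedanib against vehicle 1 reached the 92 genes (highest other 1) and 2 reached the 15 lists (highest other 15). With the block 2 reached the 6 genes (highest other 16), and for nintedanib against control 1 reached the 784 genes (highest other 645, a split that puts arrays 89 and 91 with control 50, which points to a structure of the arrays). Without the block, only the real split reached each gene count. For both list counts, and for the genes with the block, another split gave as many or more. Such counts were thus rare among the splits, but chance is not excluded for them. The runs were as uneven between groups as in the real split, with a share difference of 0.567, in 1 of the other splits of nintedanib against vehicle, so these splits say little about the run.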
